A study of Mus musculus with 30 samples.

How the data were processed

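The deposited values are RMA intensities on a linear scale, background-corrected and normalised between arrays, for 22716 probe sets on each of 30 single-channel, biotin-labelled Affymetrix mouse HT arrays. RMA (robust multi-array average) is named in the submitters' processing notes; its version, software and settings are not given in the sources used here. The log2 of each deposited intensity was taken, with no pseudocount and no further normalisation in the reported values. A gene table listed 18290 of the probe sets, of which 18003 had 1 gene and 287 several; 4336 others had no gene listed and 90 were control probe sets. Gene symbols matched the RefSeq table of assembly GRCm38.p6 in 99.8% of cases, and that table was used for names and for the order of genes along chromosomes. No genome build is named for the arrays, so no coordinates are given. Of 11807 genes, 4150 had over 1 probe set, and each gene was represented by its probe set with the highest mean over the 30 arrays among those with 1 gene. A gene was tested if its probe set lay above the 40th percentile of its array, an intensity of 16.3 to 18.1, in at least 2 arrays, which kept 8476 genes and left out 3331.

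Groups follow strain, stimulus and time, 18 in all. The labels give 22 arrays as individual mice and 8 as pools; what was pooled is not given in the sources used here, and all PAM and polyIC arrays are pools while all unstimulated and LPS arrays are individual mice. The titles and descriptions of the 4 arrays at 2 h of PAM or polyIC name opposite strains. They are called libraries titled B6 or D2 throughout, and no main fit assigns them a strain. Each pair holds 1 array of each strain under either reading, so a pair's mean does not depend on it. No group was tested for single outlying arrays, since groups held 1 or 2; array weights and leaving out arrays were tried as alternatives.

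Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, jsonlite 2.0.0 for reading labels), with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p under 0.05. Ligand effects at 6 h and of LPS at 2 h came from a fit of condition and strain over the 14 parental arrays with undisputed strain (8 residual degrees of freedom). Comparisons with 2 h of PAM or polyIC came from all 18 parental arrays, with the disputed ones midway between the strains (10 residual degrees of freedom). Strain differences at rest and after LPS, their interaction, and a moderated F test over 8 strains came from a fit of 1 mean per group to the 20 arrays of groups with 2 mice (10 residual degrees of freedom). The 6 BXD strains were compared with the parents on strain means. A strain's position between the parents is the median of its distance from D2 as a share of the parental difference after LPS. It was taken over genes called between unstimulated parents with a parental difference after LPS of at least 1 on the log2 scale. The strain of single arrays was checked by the sign of their difference over genes called the same way at rest and after LPS.

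There were 25 fixed lists of genes, namely cytokines and chemokines, interferon-stimulated antiviral genes, guanylate-binding proteins and immunity-related GTPases, interferon ligands, NF-kappaB pathway and feedback inhibitors, immediate early genes, dendritic cell maturation, MHC class I, MHC class II, pattern recognition receptors and adaptors, cell cycle, cholesterol biosynthesis, glycolysis, oxidative phosphorylation and citric acid cycle, redox and metal stress, the Ifi200 family, known parental alleles, and markers of macrophages, conventional and plasmacytoid dendritic cells, granulocytes, lymphocytes, mast cells and basophils, erythroid cells, and housekeeping genes. Of their names 1, Rigi, matched no gene. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry as alternatives, adjusted over lists within a comparison. For the 8 strains Fisher's exact test, two-sided, against all genes tested was used. The genes named in a comparison are the 8 largest rises and 8 largest falls among genes called and changed in the same direction in every strain or replicate pair. In strain comparisons 6 of each were taken, and for the 8 strains the 10 with the highest F. Up to 4 called members of each list with the largest change, and the known parental alleles, were added. Lists, models, filter, this rule and most alternatives were set before the data were examined; the exceptions are named where they are used.

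Alternatives were averaged probe sets, no filter or a 60th percentile filter, cyclic loess, array weights, and a trended and robust prior. Each array was also centred on the median level of the 11 measured housekeeping genes. That centre rests on the gene of middle level and need not follow the change of most of these genes. Other alternatives were fits to the compared arrays alone, each array left out in turn, blocks by the numbers in the descriptions, and either strain reading of the disputed arrays. On simulated data with 100 genes changed per size among 8476, the models recovered 70% (interaction) to 98% of 2-fold changes and 94% to 100% of 4-fold changes, with 2.53% to 7.46% of calls false. For the comparison of LPS at 6 h with unstimulated cells, 93% of 2-fold changes were recovered. The simulated arrays held no differences between strains. The 98%, which belongs to the BXD means against the parents, is therefore likely too high. The same holds for the fits with the disputed arrays midway between the strains. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets with several genes or controls entered no comparison, and those with no gene listed were examined apart.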

Results

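Gene expression was measured on 30 Affymetrix mouse arrays of dendritic cells grown from bone marrow of female mice aged 12 weeks. The mice were C57BL/6J (B6), DBA/2J (D2) or 1 of 6 BXD strains (BXD2, BXD5, BXD14, BXD16, BXD28 and BXD40), which are inbred mosaics of the B6 and D2 genomes. The 18 groups held 2 mice of each of the 8 strains after 6 h of lipopolysaccharide (LPS, the ligand of TLR4) and 2 unstimulated mice each of B6 and D2. They also held 1 array per parental strain after 2 h of LPS and after 6 h of PAM (Pam3CSK, a lipopeptide ligand of TLR2) or polyIC (double-stranded RNA, sensed by TLR3 and by RIG-I-like receptors). The last 4 arrays, 2 after 2 h of PAM and 2 after 2 h of polyIC, carry titles and descriptions that name opposite parental strains, and each is called here the library titled B6 or the library titled D2. The 8 PAM and polyIC arrays are labelled as pools and the other 22 as individual mice. The descriptions of the unstimulated and LPS arrays of B6 and D2 share 4 mouse numbers. Whether equal numbers mean the same mouse is not given, and the main fits treat these arrays as separate. Median intensities were 31.2 to 31.7 in the unstimulated arrays and lower, 27.3 to 29.6, in all stimulated arrays. Every comparison with unstimulated cells carries this offset, and its cause was not tested. The 2 mice of a group correlated across genes at 0.988 to 0.997. The small number of arrays limits the precision, and p-values measure the spread between these arrays alone. All changes are on the log2 scale with their standard error. A mean level under 4.17, the highest filter level of an array, is not told from background here. A change with 1 side there is a smallest size, written as at least its value or, for a fall, as its value or lower. The genes given as the largest rises and falls moved the same way in each strain or replicate pair of their comparison.

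The LPS comparisons ask which genes parental dendritic cells turn on and off after TLR4 engagement. After 6 h, Cxcl10, which draws activated T cells, rose by 8.23 ± 0.16 (adjusted p = 2.04e-11; mean level 12.97 against 4.74; n = 4 against 4). Ptgs2, which makes prostaglandin precursors, rose by at least 8.06 ± 0.27, Il12b, a subunit of IL-12 and IL-23, by 7.81 ± 0.30, and the cytokine Il6 by 7.75 ± 0.38 (adjusted p = 8.18e-09). The largest falls were in Pald1, a phosphatase-like protein (-4.61 ± 0.18 or lower, adjusted p = 1.86e-09), and Ppargc1b, a coactivator of mitochondrial and lipid genes (-4.47 ± 0.13, adjusted p = 2.13e-10). Of 8476 genes tested, 2307 rose and 3672 fell, of which 680 and 1149 changed at least 2-fold.

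The fixed gene lists showed an inflammatory and an interferon programme. Of 35 measured cytokines and chemokines, 34 rose and 1 did not pass (camera adjusted p = 2.52e-16, or adjusted p = 0.00927 with an estimated correlation; 34 adjusted over the list alone), with a median change of 3.67. All 36 interferon-stimulated antiviral genes rose (adjusted p = 3.71e-24, or adjusted p = 0.111 with an estimated correlation). They include Oasl1 (7.35 ± 0.16), Cmpk2 (7.35 ± 0.27) and Ifit2 (7.30 ± 0.17). Among guanylate-binding proteins and immunity-related GTPases, which attack intracellular pathogens, 11 of 13 rose, Iigp1 by at least 7.41 ± 0.31 and Tgtp1 by 6.59 ± 0.22 (adjusted p = 1.53e-08, or adjusted p = 0.111 with an estimated correlation). All 5 measured members of the Ifi200 family of DNA sensors rose, Ifi204 by 4.84 ± 0.25 (adjusted p = 8.96e-04, or adjusted p = 0.111 with an estimated correlation). In the NF-kappaB pathway and its feedback inhibitors, 23 of 25 rose (adjusted p = 1.13e-11, or adjusted p = 0.0544 with an estimated correlation), among them the STAT3 inhibitor Socs3 (4.91 ± 0.21) and Nfkbiz (4.59 ± 0.22). Of 22 maturation genes, 20 rose and 1 fell (adjusted p = 1.72e-09, or adjusted p = 0.181 with an estimated correlation; 21 adjusted over the list alone). The co-stimulatory receptor Cd40 rose by 6.00 ± 0.31, Il15 by 3.78 ± 0.19 and Cd70 by at least 3.66 ± 0.28.

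Antigen presentation and sensing genes split. MHC class I genes rose in 9 of 12 and fell in 1 (adjusted p = 0.00101, or adjusted p = 0.244 with an estimated correlation), led by Tapbpl (2.03 ± 0.11) and the immunoproteasome subunits Psmb9 (1.51 ± 0.10) and Psmb10 (1.34 ± 0.09). Of 12 class II genes, 1 rose and 4 fell (adjusted p = 0.626), H2-DMa, which loads peptides, by -1.37 ± 0.13. Among 24 receptors and adaptors, 14 rose and 8 fell (adjusted p = 0.0245, or adjusted p = 0.244 with an estimated correlation). Tlr3 rose by 3.76 ± 0.17, whereas Tlr4, the LPS receptor itself, fell (-1.98 ± 0.11). Immediate early genes rose in 8 and fell in 6 of 23 and did not pass as a list (adjusted p = 0.0848), and the split turned to 6 and 7 when arrays were centred on housekeeping genes. The stress factors Plk2 (2.71 ± 0.21) and Gadd45b (2.68 ± 0.10) rose, and the transcription factors Egr2 (-3.08 ± 0.23) and Klf4 (-2.82 ± 0.23) fell.

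Cell-cycle, respiratory and cholesterol genes fell as lists at the preset correlation only. Of 32 cell-cycle genes, 27 fell and 2 rose (adjusted p = 3.09e-04, or adjusted p = 0.471 with an estimated correlation; 29 adjusted over the list alone), including Ccna2 (-2.90 ± 0.32), Birc5 (-2.88 ± 0.27) and Rrm2 (-2.62 ± 0.29), which act in replication and mitosis. Of 33 genes of oxidative phosphorylation and the citric acid cycle, 30 fell and none rose (adjusted p = 1.46e-05, or adjusted p = 0.271 with an estimated correlation), Idh1 by -2.32 ± 0.12, Idh3a by -1.82 ± 0.13 and Fh1 by -1.69 ± 0.11. Cholesterol synthesis genes fell in 12 of 17 and rose in 1 (adjusted p = 0.0289, or adjusted p = 0.445 with an estimated correlation; 13 adjusted over the list alone), led by Dhcr7 (-2.12 ± 0.25), while the sterol carrier Stard4 of the same list fell by -1.97 ± 0.15. Glycolysis genes went both ways, 5 of 14 up and 6 down (adjusted p = 0.904), as did redox and metal stress genes with 4 of 16 up and 5 down (adjusted p = 0.683), and cyclic loess turned the latter to 5 and 4. The median of all genes shifted by -0.14 after 6 h and 2 h of LPS, and relative to it the respiratory list had a median of -0.35. Cyclic loess between arrays gave 2953 genes up and 2774 down, and centring on housekeeping genes 1200 and 4732; the directions of the other lists held under both scalings, as did those of genes called at 2-fold or more.

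Markers of other cells were measured beside these. Of 13 macrophage markers, 4 rose and 5 fell (adjusted p = 0.706), Marco by 3.49 ± 0.51 up and Csf1r by -1.77 ± 0.17 down. Of 10 conventional dendritic cell markers, 2 rose and 4 fell (adjusted p = 0.928), of 7 plasmacytoid markers 3 rose and 1 fell (adjusted p = 0.0935), and of 11 granulocyte markers 3 rose and 3 fell (adjusted p = 0.904). No lymphocyte (2 of 5 up), mast cell or basophil (2 of 4 up) or erythroid marker (2 of 6 up) fell. The erythroid marker Slc4a1 lay under the filter level on both sides, so its rise is not told from background. The lymphocyte markers Ly6d and Cd3e rose from levels under it. Of 11 housekeeping genes, 8 fell with 1 up (adjusted p = 0.15). Of 6 genes with known parental alleles, 3 fell.

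After 2 h of LPS Ifnb1 stood high. The gene, which encodes interferon beta, rose by at least 7.13 ± 0.38 (adjusted p = 6.79e-08; mean level 11.22 against 4.09; n = 2 against 4), and all 4 measured interferon ligands rose (adjusted p = 1.93e-04, or adjusted p = 0.0994 with an estimated correlation), Ifna4 by at least 2.69 ± 0.39 to a level of 6.13. At this time 34 of 36 interferon-stimulated genes (adjusted p = 0.0628 with an estimated correlation; 35 adjusted over the list alone), 28 of 35 cytokines (adjusted p = 0.00384 with an estimated correlation) and 21 of 25 NF-kappaB genes (adjusted p = 0.0101 with an estimated correlation) were already up and none was down. Ptgs2 rose by at least 8.07 ± 0.33, Cxcl1, which attracts neutrophils, by 7.72 ± 0.51, and Nfkbiz by 5.82 ± 0.27. Immediate early genes rose in 14 of 23 and fell in 4 (adjusted p = 1.01e-05, or adjusted p = 0.118 with an estimated correlation), with Maff at 3.35 ± 0.32 and Egr1 at 2.52 ± 0.42. Falls were led by Ppargc1b (-3.99 ± 0.16), the mRNA decay factor Zfp36l2 (-3.57 ± 0.40) and the receptor chain Il6ra (-3.29 ± 0.30); 20 of 32 cell-cycle genes fell and 1, Mki67, rose (1.86 ± 0.33; list adjusted p = 0.665 with an estimated correlation). In total 1228 genes rose and 2654 fell, and cyclic loess gave 1695 and 1583. Without the B6 array at 2 h of LPS 2487 genes were called.

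Between 2 h and 6 h of LPS no list passed with an estimated correlation. Ifnb1 fell by 4.62 ± 0.38 (adjusted p = 5.42e-06; n = 4 at 6 h against 2 at 2 h), F3, the initiator of clotting, fell by 4.34 ± 0.30, and Maff, Fos and Jun fell by 2.77 ± 0.32, 2.47 ± 0.20 and 1.87 ± 0.19. Immediate early genes fell in 11 of 23 and rose in 1, and did not pass as a list (adjusted p = 0.0586). Ms4a4c, a membrane protein of myeloid cells, rose by 4.88 ± 0.30 (adjusted p = 1.09e-06), Nos2, which makes nitric oxide, by at least 3.31 ± 0.31, Isg20 by 3.07 ± 0.18 and Il18 by 2.82 ± 0.23. Interferon-stimulated genes rose in 23 of 36 and fell in 1 (adjusted p = 6.71e-09), the GTPases rose in 9 of 13, and MHC class I genes rose in 8 of 12 (adjusted p = 3.14e-04); none of the 3 passed with an estimated correlation (adjusted p = 0.416 with an estimated correlation for each). Interferon ligands fell in 3 of 4 (adjusted p = 0.0205, or adjusted p = 0.416 with an estimated correlation), cholesterol genes in 7 of 17 and respiratory genes in 12 of 33. Cytokines rose in 10 and fell in 2, which housekeeping centring turned to 7 and 9. Counts were 1587 up and 1755 down, 764 and 3659 after housekeeping centring, and 2107 in all without the B6 array at 2 h.

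**Figure D1:**
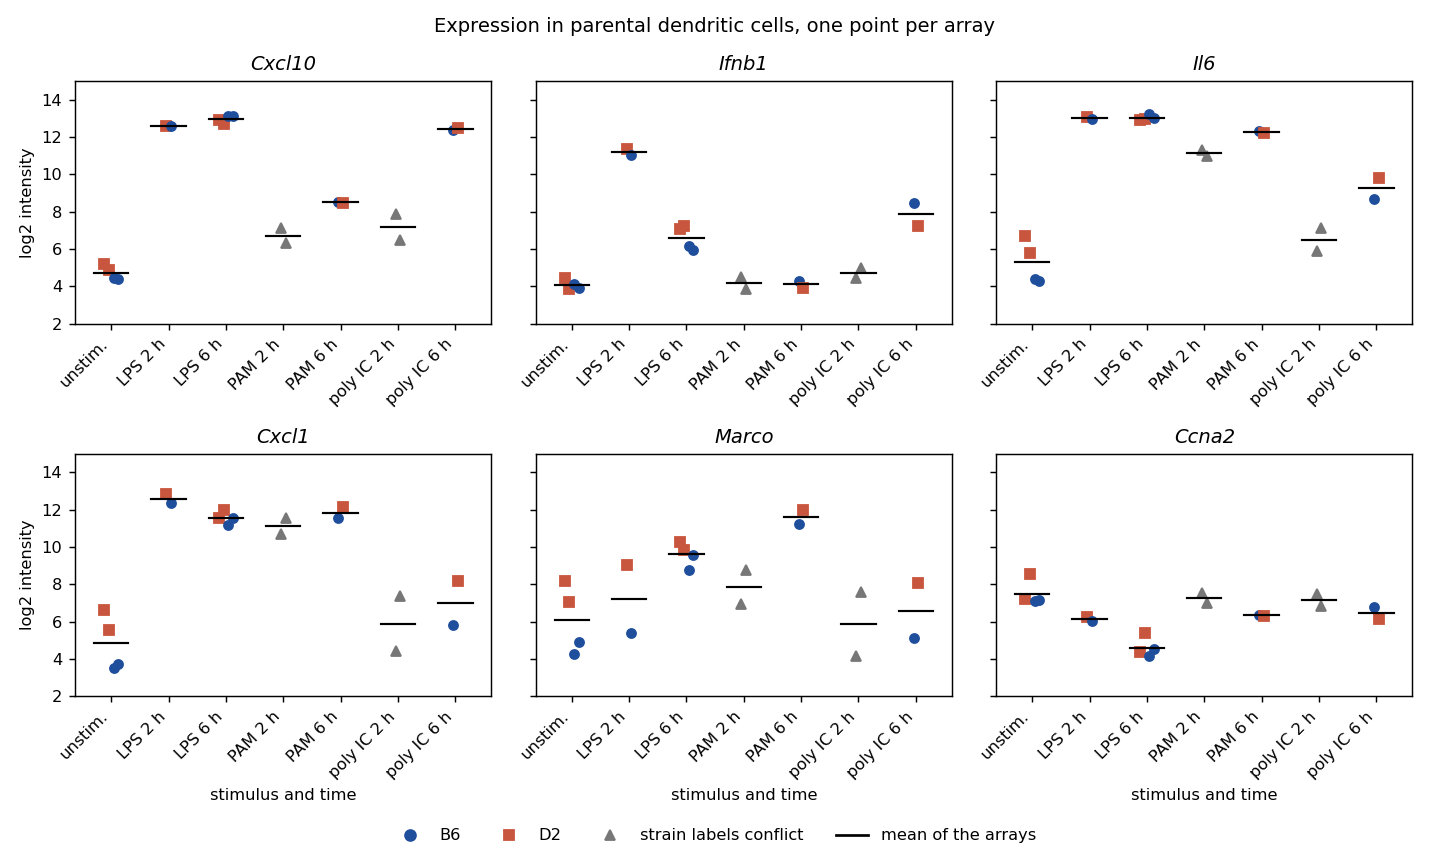
Log2 intensity of Cxcl10, Ifnb1, Il6, Cxcl1, Marco and Ccna2 (vertical axis) in each parental array by stimulus and time (horizontal axis). Blue circles are B6, red squares D2, grey triangles the 4 arrays whose labels name opposite strains, and lines are group means; Ifnb1 stands at 11.22 after 2 h of LPS and at 4.09 in unstimulated cells.

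PAM at 6 h asks what TLR2 engagement changes. Il6 rose by 6.99 ± 0.46 (adjusted p = 2.54e-06; n = 2 against 4), as did Cxcl1 by 6.99 ± 0.51, the neutrophil chemokine Cxcl5 by 5.65 ± 0.58 and Tnf by 5.01 ± 0.28. The scavenger receptor Marco rose by 5.48 ± 0.62 (adjusted p = 7.77e-05; mean level 11.58 against 6.10), and the haem-degrading enzyme Hmox1 by 3.50 ± 0.17. Ifnb1 did not pass, with mean levels of 4.11 and 4.09. Clec10a, a lectin of dendritic cells, fell by 2.87 ± 0.27 (adjusted p = 2.42e-05), Klf4 by 2.85 ± 0.29 and the mannose receptor Mrc1 by 2.09 ± 0.29. Cytokines rose in 24 of 35 (adjusted p = 3.75e-16, or adjusted p = 0.00962 with an estimated correlation; 25 adjusted over the list alone). NF-kappaB genes rose in 17 of 25 and fell in 1 (adjusted p = 2.48e-09, or adjusted p = 0.102 with an estimated correlation; 19 adjusted over the list alone), including the RNase Zc3h12a (2.77 ± 0.14). Interferon-stimulated genes rose in 29 of 36 (adjusted p = 1.06e-16, or adjusted p = 0.218 with an estimated correlation; 31 adjusted over the list alone), Ifit1 by 4.15 ± 0.37, Cmpk2 by 3.29 ± 0.33 and Cxcl10 by 3.77 ± 0.20, while none of the 4 interferon ligands passed. Cell-cycle genes fell in 22 of 32 and rose in 1 (adjusted p = 7.32e-08, or adjusted p = 0.49 with an estimated correlation; 25 adjusted over the list alone), among them Mcm6 (-1.84 ± 0.33) and Bub1b (-1.73 ± 0.25). Conventional dendritic cell markers fell in 5 of 10 (adjusted p = 0.0094, or adjusted p = 0.144 with an estimated correlation). Across all genes 1162 rose and 1644 fell, and housekeeping centring gave 595 and 2900. Without the B6 pool 1346 genes were called and without the D2 pool 1830. The PAM and polyIC arrays are pools and the unstimulated arrays are not, and 352 of the rises and 343 of the falls also differed in the same direction from the polyIC pools.

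PolyIC at 6 h asks the same of double-stranded RNA sensing. Cxcl10 rose by 7.69 ± 0.20 (adjusted p = 7.64e-10; mean level 12.43; n = 2 against 4), followed by Ifit3 (6.79 ± 0.28), Ifit2 (6.57 ± 0.21), Rsad2 (6.21 ± 0.26) and Isg20 (5.94 ± 0.18). All 36 interferon-stimulated genes rose (adjusted p = 3.52e-43, or adjusted p = 0.036 with an estimated correlation), with 10 of 13 GTPases (adjusted p = 3.35e-14, or adjusted p = 0.036 with an estimated correlation) and all 5 Ifi200 genes (adjusted p = 8.61e-06, or adjusted p = 0.0362 with an estimated correlation). Interferon ligands rose in 3 of 4 (adjusted p = 0.002, or adjusted p = 0.172 with an estimated correlation), Ifnb1 by at least 3.76 ± 0.38. Of the 3, Ifna5 lay under the filter level on both sides (4.08 and 3.25), so its rise is not told from background. Cytokines rose in 21 of 35 (adjusted p = 1.5e-09, or adjusted p = 0.036 with an estimated correlation), the monocyte attractant Ccl12 by at least 4.85 ± 0.42, Il6 by 3.96 ± 0.46 and Tnf by 3.58 ± 0.28. MHC class I genes rose in 8 of 12 and fell in 2 (adjusted p = 7.68e-05, or adjusted p = 0.152 with an estimated correlation), and the sensor Tlr3 rose by 3.02 ± 0.20. Cell-cycle genes fell in 14 of 32 and rose in 1 (adjusted p = 6.13e-04, or adjusted p = 0.484 with an estimated correlation), and the rise was in Ccnd1 (1.69 ± 0.27). Other falls were in Fasn, which makes fatty acids (-1.85 ± 0.29), and the noncoding RNAs Airn (-1.88 ± 0.35 or lower) and Neat1 (-1.78 ± 0.40), both of which were also called lower in the other 3 pooled conditions. In total 994 genes rose and 1400 fell; loess gave 1199 and 1015, and housekeeping centring 1275 and 886. Without the B6 pool 1163 genes were called and without the D2 pool 1381. Of the rises 397, and of the falls 207, also differed in the same direction from the PAM pools.

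Direct comparisons at 6 h asked how the ligands differ. PAM exceeded polyIC (n = 2 against 2) in Cxcl5 (5.07 ± 0.67, adjusted p = 3.69e-04), Marco (5.0 ± 0.72, adjusted p = 6.86e-04), Cxcl1 (4.85 ± 0.59), the iron-binding Lcn2 (3.97 ± 0.34) and Csf3 (at least 3.78 ± 0.61). PolyIC exceeded PAM in Iigp1 (-5.31 ± 0.44, adjusted p = 1.68e-05), Cxcl11 (-4.78 ± 0.79 or lower), Ifit3 (-4.33 ± 0.32), Cxcl10 (-3.92 ± 0.23), Ifnb1 (-3.74 ± 0.44 or lower) and Tlr3 (-3.62 ± 0.24). Marco is also a macrophage marker, and Mrc1 of the same list was lower after PAM (-1.53 ± 0.34). Lower too were the conventional dendritic cell markers Dpp4 (-1.49 ± 0.24) and Mgl2 (-1.08 ± 0.26) and the granulocyte marker S100a9 (-1.31 ± 0.31). Interferon-stimulated genes were lower after PAM in 33 of 36 (adjusted p = 3.03e-32, or adjusted p = 0.09 with an estimated correlation), and GTPases in 10 of 13. No list passed with an estimated correlation in this comparison. Cytokines were higher after PAM in 15 and lower in 2 of 35 (adjusted p = 2.27e-04, or adjusted p = 0.0996 with an estimated correlation), and redox genes higher in 5 of 16 (adjusted p = 0.00154, or adjusted p = 0.09 with an estimated correlation). In the NF-kappaB list 4 were higher and none lower, which housekeeping centring turned to 4 and 5. Of the 1369 genes called, 630 were higher after PAM and 739 lower, and housekeeping centring gave 200 and 2474. Leaving out 1 pool gave 632 (B6 PAM), 684 (D2 polyIC), 716 (B6 polyIC) or 740 (D2 PAM).

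The LPS arrays compared next are individual mice and the PAM and polyIC arrays pools. Against PAM, LPS (n = 4 against 2) was higher in Iigp1 (6.81 ± 0.38, adjusted p = 1.39e-07), Cxcl11 (at least 6.40 ± 0.68), Cxcl9 (5.58 ± 0.28), Tlr3 (4.36 ± 0.20), Nos2 (at least 3.56 ± 0.31) and Ifnb1 (at least 2.48 ± 0.38). It was lower in Gadd45a, a stress sensor (-3.95 ± 0.34), Hmox1 (-3.05 ± 0.17), the transcription factor Cebpa (-2.90 ± 0.18) and Marco (-1.99 ± 0.62). Interferon-stimulated genes were higher in 34 of 36 (adjusted p = 1.16e-24, or adjusted p = 0.101 with an estimated correlation) and maturation genes in 18 of 22 (adjusted p = 3.74e-09, or adjusted p = 0.156 with an estimated correlation). The same held for NF-kappaB genes in 17 of 25 (adjusted p = 2.93e-06, or adjusted p = 0.117 with an estimated correlation) and cytokines in 18 of 35 with 3 lower (adjusted p = 1.1e-05, or adjusted p = 0.101 with an estimated correlation; 19 and 3 adjusted over the list alone). No list passed with an estimated correlation in this comparison. Counts were 1512 higher and 2791 lower, or 1990 and 1979 after loess. Against polyIC, LPS (n = 4 against 2) was higher in Ptgs2 (6.81 ± 0.33, adjusted p = 2.72e-07), Il12b (6.65 ± 0.36), Il12a (4.66 ± 0.32), Il23a (4.18 ± 0.30) and the co-stimulator Cd80 (2.67 ± 0.29). It was lower in Ppargc1b (-3.64 ± 0.16), Fos (-2.35 ± 0.20), Idh1 (-1.94 ± 0.15) and Ifnb1 (-1.25 ± 0.38). Cytokines were higher in 29 of 35 (adjusted p = 0.013 with an estimated correlation), interferon-stimulated genes in 17 of 36 (adjusted p = 0.635 with an estimated correlation) and NF-kappaB genes in 16 of 25 (adjusted p = 0.0761 with an estimated correlation). Respiratory genes were lower in 25 of 33 and higher in 1 (adjusted p = 4.94e-06, or adjusted p = 0.442 with an estimated correlation; 29 and 1 adjusted over the list alone). Counts were 1410 higher and 2481 lower, 1932 and 1840 after loess, and 484 and 4776 after housekeeping centring. Without the B6 polyIC pool 2424 genes were called.

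**Figure D2:**
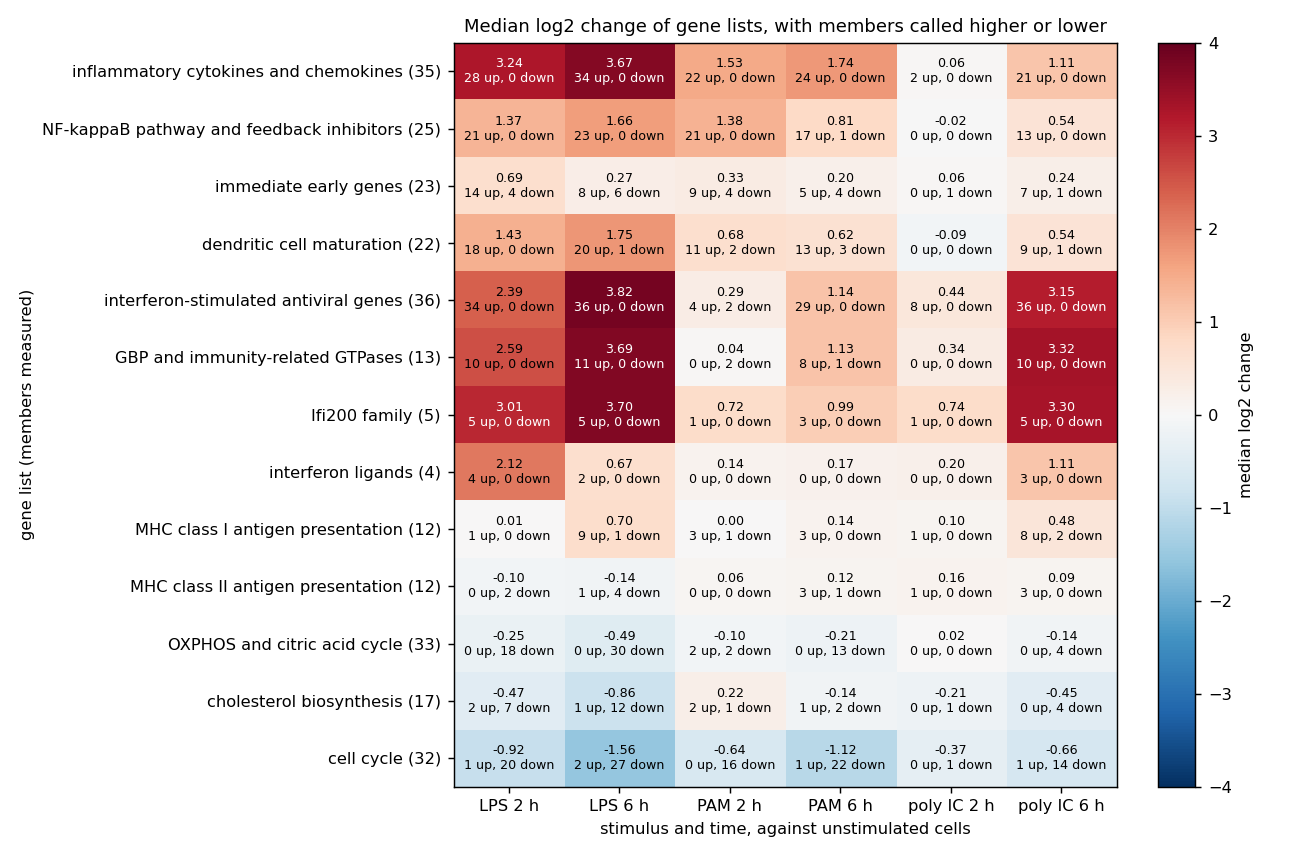
Heat map of the median log2 change against unstimulated cells of 13 fixed gene lists (vertical axis) in 6 stimulus and time conditions (horizontal axis), with the number of members higher and lower in each cell. The interferon-stimulated list has a median of 3.82 after 6 h of LPS, 1.14 after PAM and 3.15 after polyIC; after 2 h of PAM its split of 4 higher and 2 lower turns to 3 and 4 when arrays are centred on housekeeping genes.

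At 2 h, PAM and polyIC were compared with unstimulated cells without assigning a strain to the disputed arrays. Genes differing between strains therefore have wide errors there (1.93 for H2-Ea after PAM). After PAM, Cxcl1 rose by 6.29 ± 0.70 (adjusted p = 3.39e-05; n = 2 against 4), Il6 by 5.85 ± 0.48, Il12b by 5.38 ± 0.46, Nfkbiz by 5.09 ± 0.26 and Zc3h12a by 2.99 ± 0.13, and Ppargc1b (-3.71 ± 0.17), the signalling regulator Rgs2 (-2.77 ± 0.30) and Klf4 (-2.69 ± 0.35) fell. NF-kappaB genes rose in 21 of 25 (adjusted p = 5.31e-20, or adjusted p = 0.0134 with an estimated correlation; 22 adjusted over the list alone) and cytokines in 22 of 35 (adjusted p = 4.87e-15, or adjusted p = 0.045 with an estimated correlation; 24 adjusted over the list alone). Interferon-stimulated genes rose in 4 and fell in 2 of 36 (adjusted p = 0.0258, or adjusted p = 0.89 with an estimated correlation), a split that housekeeping centring turned to 3 and 4. After PAM 914 genes rose and 1685 fell, 1187 and 1272 after loess and 530 and 2264 after housekeeping centring, and 1529 were called without the PAM library titled D2 and 1632 with array weights. Of these calls 376 and 597 also differed in the same direction from the polyIC pools of that time.

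After 2 h of polyIC, Hmox1 (2.67 ± 0.16, adjusted p = 2.41e-06; n = 2 against 4), Cxcl10 (2.42 ± 0.33, adjusted p = 0.00124), Ifit1 (2.12 ± 0.41) and Rsad2 (1.70 ± 0.31) rose. Hmox1, Cxcl10 and Rsad2 also rose in the PAM pools of that time, by 3.13, 1.98 and 1.87. Such shared rises cannot be told from an effect of pooling. The largest falls were in Airn (-2.28 ± 0.34 or lower), Gsap (-2.23 ± 0.26) and the RNA-binding Fubp1 (-2.23 ± 0.38). Interferon-stimulated genes rose in 8 of 36 (adjusted p = 8.74e-08, or adjusted p = 0.694 with an estimated correlation; 14 adjusted over the list alone), 2 cytokines rose, and no NF-kappaB gene passed. Counts were 138 up and 333 down, or 70 and 399 after housekeeping centring. They came to 180 in all without the polyIC library titled D2, 170 without that titled B6 and 282 without B6 unstimulated replicate 1. Of the calls 19 rises and 36 falls also differed from the PAM pools of that time.

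Comparing both pools at 2 h, PAM was higher in Il12b (5.58 ± 0.53, adjusted p = 2.93e-05; n = 2 against 2), Il6 (4.62 ± 0.56) and Rel (2.78 ± 0.19) and lower in Rgs2 (-3.13 ± 0.35) and Ppargc1b (-2.88 ± 0.19). NF-kappaB genes were higher in 21 of 25 (adjusted p = 0.00335 with an estimated correlation) and cytokines in 16 of 35 (adjusted p = 0.0245 with an estimated correlation). This comparison, and those between 6 h and 2 h of PAM or polyIC, were added after the data were seen. Counts were 464 higher and 709 lower, 558 and 516 after loess and 340 and 854 after housekeeping centring. They came to 382 with array weights, 493 without the polyIC library titled D2 and 626 without the PAM library titled D2.

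From 2 h to 6 h of PAM (n = 2 against 2), Ifit1 (3.02 ± 0.47, adjusted p = 0.00215), Cmpk2 (2.79 ± 0.47) and Usp18 (2.57 ± 0.31) rose, and 19 of 36 interferon-stimulated genes rose (adjusted p = 0.397 with an estimated correlation). The co-stimulators Cd70 (-2.20 ± 0.46) and Tnfsf9 (-2.11 ± 0.35) fell, as did Rel (-1.46 ± 0.19), and NF-kappaB genes fell in 8 of 25 (adjusted p = 4.88e-08, or adjusted p = 0.283 with an estimated correlation). Counts were 643 up and 362 down, or 374 and 432 after housekeeping centring, 585 in all with array weights, and 287, 359 or 370 in all without the B6 PAM pool at 6 h, the PAM library titled D2 or the D2 PAM pool at 6 h. From 2 h to 6 h of polyIC (n = 2 against 2), Iigp1 (at least 5.77 ± 0.42, adjusted p = 1.57e-06), Ifit2 (5.53 ± 0.30), Cxcl10 (5.26 ± 0.38), Ccl12 (at least 4.80 ± 0.51) and Ifnb1 (3.14 ± 0.44) rose, and the growth regulator Sesn1 (-1.53 ± 0.14) and the checkpoint protein Vsir (-1.54 ± 0.27) fell. Interferon-stimulated genes rose in 31 of 36 (adjusted p = 0.0264 with an estimated correlation) and NF-kappaB genes in 8 of 25 (adjusted p = 0.0353 with an estimated correlation). Counts were 471 up and 301 down, 532 and 214 after loess and 631 and 83 after housekeeping centring. They came to 327 without the D2 polyIC pool at 6 h, 353 without the B6 pool and 364 without the polyIC library titled D2.

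The comparison of B6 and D2 at rest asks how the parental cells differ before any ligand. H2-Ea, a class II chain whose gene carries a deletion in B6, was lower in B6 (-8.18 ± 0.11 or lower, adjusted p = 2.78e-16; mean level 12.18 in D2 and under the filter level in B6; n = 2 against 2). The Ifi200 gene Ifi202b (-6.95 ± 1.10 or lower, adjusted p = 5.48e-04), arginase Arg1 (-6.02 ± 0.52) and the chitinase-like Chil1 (-4.95 ± 0.23 or lower) were also lower in B6. Cav1, the caveola protein, was higher in B6 by 7.06 ± 0.22 (adjusted p = 2.41e-11; mean level 11.44 against 4.37), as was Gpnmb, which carries a stop mutation in D2, by 6.30 ± 0.33. Of 6 genes with known parental alleles, Nnt (-1.21 ± 0.17), Glo1 (-1.19 ± 0.15) and Alad (-1.38 ± 0.24) were lower in B6 and Klrd1 higher (at least 1.30 ± 0.12).

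Unstimulated D2 cells carried more interferon-stimulated RNA. B6 was lower in 27 of 36 such genes and higher in none (adjusted p = 1.02e-19, or adjusted p = 0.131 with an estimated correlation; 28 adjusted over the list alone), with Rtp4 at -2.25 ± 0.17, Oasl2 at -2.11 ± 0.17 and Ifitm3 at -2.07 ± 0.16. GTPases were lower in 5 of 13 and higher in 1 (adjusted p = 0.00537, or adjusted p = 0.46 with an estimated correlation), and cytokines lower in 9 and higher in 2 of 35 (adjusted p = 4.84e-04, or adjusted p = 0.149 with an estimated correlation; 11 adjusted over the list alone), with Cxcl5 at -3.45 ± 0.43 or lower and Il1a at -2.55 ± 0.18. Cell-cycle genes were lower in 14 of 32 (adjusted p = 2.95e-08, or adjusted p = 0.37 with an estimated correlation; 21 adjusted over the list alone), such as Bub1 (-1.36 ± 0.18) and Mki67 (-1.26 ± 0.20), and glycolysis genes in 4 of 14 (adjusted p = 0.00114, or adjusted p = 0.202 with an estimated correlation; 7 adjusted over the list alone). Class II genes were higher in B6 in 9 of 12 (adjusted p = 2.01e-10, or adjusted p = 0.0314 with an estimated correlation; 10 adjusted over the list alone). They included the class II transactivator Ciita (2.07 ± 0.27) and H2-Ab1 (1.61 ± 0.13). Cholesterol genes were higher in 9 of 17 (adjusted p = 3.88e-08, or adjusted p = 0.198 with an estimated correlation; 13 adjusted over the list alone), with Sc5d at 1.72 ± 0.18. Macrophage markers were higher in 2 and lower in 1 of 13 (adjusted p = 0.737), and 3 of 7 plasmacytoid markers were higher (adjusted p = 0.0118, or adjusted p = 0.187 with an estimated correlation). The conventional dendritic cell markers Mgl2 (1.09 ± 0.30), Dpp4 (0.91 ± 0.26) and Flt3 (at least 0.77 ± 0.17) were also higher in B6. The granulocyte marker Mmp9 was lower in B6 (-3.32 ± 0.46). In all 480 genes were higher in B6 and 549 lower, or 278 and 863 after housekeeping centring. Leaving out 1 array gave 620 (D2 replicate 2), 633 (B6 replicate 2) or 641 (B6 replicate 1).

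After 6 h of LPS, B6 and D2 (n = 2 against 2) still differed in Ifi202b (-8.57 ± 1.10, adjusted p = 8.82e-05), H2-Ea (-8.15 ± 0.11 or lower), Arg1 (-5.70 ± 0.52), Cav1 (6.73 ± 0.22, adjusted p = 4.87e-11), Ifi205 (5.95 ± 0.22) and Gpnmb (5.37 ± 0.33). The transcription factor Lhx2 was higher in B6 by at least 4.61 ± 0.21 (adjusted p = 1.19e-09), and the T cell attractant Cxcl11 (-3.30 ± 0.19), the alarmin Il33 (-2.59 ± 0.35) and Ifnb1 (-1.10 ± 0.25) were lower. Glycolysis genes were lower in B6 in 12 of 14 (adjusted p = 5.33e-08, or adjusted p = 0.0878 with an estimated correlation; 12 adjusted over the list alone), among them the lactate exporter Slc16a3 (-1.85 ± 0.21) and the glucose transporter Slc2a1 (-1.50 ± 0.15). Class II genes were higher in 10 of 12 (adjusted p = 2.18e-10, or adjusted p = 0.0287 with an estimated correlation), H2-DMb1 by 1.91 ± 0.18, and cholesterol genes in 10 of 17 (adjusted p = 5.95e-09, or adjusted p = 0.19 with an estimated correlation; 11 adjusted over the list alone), Cyp51 by 2.97 ± 0.33 and Sqle by 2.54 ± 0.31. Only 2 interferon-stimulated genes were higher and 3 lower (adjusted p = 0.662), and 5 cytokines were higher and 8 lower (adjusted p = 0.601). No list of cell markers passed, but single markers differed. The plasmacytoid marker Blnk was higher in B6 (0.53 ± 0.12) and the mast cell or basophil marker Gata2 lower (-0.57 ± 0.18). Of 13 macrophage markers C1qb (2.59 ± 0.63) and Mertk (1.76 ± 0.30) were higher in B6 (adjusted p = 0.662; 4 called adjusted over the list alone). Of 10 conventional dendritic cell markers Mgl2 was higher (1.26 ± 0.30) and Batf3 lower (-0.80 ± 0.26; list adjusted p = 0.585). Of 11 granulocyte markers Mmp9 was lower (-2.50 ± 0.46; list adjusted p = 0.91). In all 703 genes were higher in B6 and 648 lower, or 321 and 1712 after housekeeping centring. Leaving out 1 array gave 741 (B6 replicate 1), 867 (D2 replicate 2) or 890 (B6 replicate 2).

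A test of the difference between strains in the LPS response called 444 genes, 266 with the larger change in B6 on the signed scale and 178 with the larger in D2, or 134 and 149 after housekeeping centring. A fit to the compared arrays alone called 259. Lhx2 went from 2.82 to 8.13 in B6 and lay at 2.88 and 3.52 in D2 (difference of the changes 4.67 ± 0.30, adjusted p = 6.06e-07; n = 2 in each of 4 groups). The lymphotoxin gene Lta (3.94 ± 0.34) and Slfn1 (3.61 ± 0.29) had the larger rise in B6, and Cxcl11 (-2.74 ± 0.27, adjusted p = 5.34e-05), Gbp2b (-2.55 ± 0.35) and Il33 (-2.26 ± 0.50) in D2. All levels of Lhx2 but 8.13, and the resting levels of Lta (3.75 in B6 and 3.55 in D2), Cxcl11 (3.42 and 3.98) and Il33 (3.73 and 4.06), lie under the filter level, so the sizes of these differences are uncertain. Interferon-stimulated genes had the larger change in B6 in 18 of 36 and in D2 in 1 (adjusted p = 2.33e-15, or adjusted p = 0.286 with an estimated correlation; 27 adjusted over the list alone). Rtp4 went from 7.56 in B6 and 9.82 in D2 to 11.75 in both. Cytokines had the larger change in B6 in 8 and in D2 in 3 of 35 (adjusted p = 0.0121, or adjusted p = 0.417 with an estimated correlation; 17 adjusted over the list alone), with Il6 at 2.10 ± 0.27 from starting levels of 4.32 in B6 and 6.25 in D2. In 3 of 32 cell-cycle genes D2 moved further down (adjusted p = 3.7e-05, or adjusted p = 0.563 with an estimated correlation; 7 adjusted over the list alone), with changes in B6 and D2 of -1.76 and -2.95 for Bub1, -0.92 and -2.10 for Mcm6 and 0.52 and -1.10 for Mki67. Bub1 after LPS lay under the filter level in both strains (3.54 and 3.71). The change was larger in B6 for 3 of 5 Ifi200 genes (adjusted p = 2.81e-04, or adjusted p = 0.286 with an estimated correlation; 4 adjusted over the list alone). Leaving out 1 array gave 206 (B6 LPS replicate 1), 248 and 266 (B6 unstimulated replicates 2 and 1), 269 (B6 LPS replicate 2), 277 (D2 unstimulated replicate 2) or 279 (D2 LPS replicate 2).

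**Figure D3:**
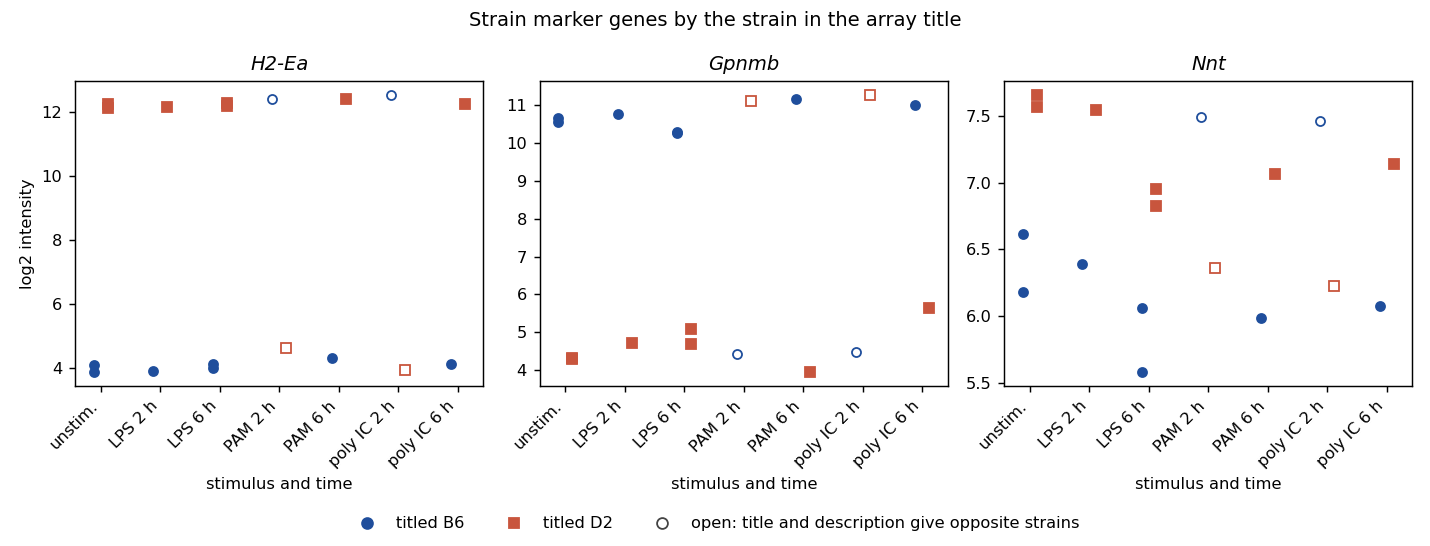
Log2 intensity of H2-Ea, Gpnmb and Nnt (vertical axis) in single parental arrays by condition and by the strain in the array title (horizontal axis and colour). Open symbols are the 4 arrays whose description names the other strain; after 2 h of PAM, H2-Ea stands at 12.40 in the library titled B6 and at 4.62 in the library titled D2.

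The titles of the 2 h pools were compared with the parental differences. Over 449 genes that differed between B6 and D2 both at rest and after LPS, single B6 and D2 arrays differed in the same direction for 97.8% of genes after 2 h of LPS, 98.0% after 6 h of PAM and 96.7% after 6 h of polyIC. For libraries taken by their titles the share was 6.68% after 2 h of PAM and 4.23% after 2 h of polyIC. H2-Ea stood at 12.52 in the polyIC library titled B6 and at 3.93 in that titled D2, and Gpnmb at 4.42 and 11.09 in the PAM libraries titled B6 and D2. For most of the genes compared, these values argue against the titles and go with the descriptions in both pairs. The main fits were left without a strain for these arrays.

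The 8 strains after 6 h of LPS show how far expression varies across the BXD panel (n = 2 mice per strain). H2-Ea ranged over at least 9.52 (F = 3385, adjusted p = 2.56e-18), with 4.07 in B6, 3.69 in BXD2 and 4.08 in BXD14 and between 12.22 and 13.21 in the other 5 strains. Pttg1, an inhibitor of chromosome separation, ranged over 4.55 (adjusted p = 1.52e-12), Ifi205 over 6.63 (adjusted p = 1.95e-12) and Cav1 over 6.73 (adjusted p = 1.78e-11). Lhx2 lay at 8.13 in B6, 8.04 in BXD28, 7.98 in BXD16 and 7.57 in BXD2, and at 4.06 or lower in D2, BXD5, BXD14 and BXD40. Cxcl11 ranged over 4.37, from 7.85 in BXD40 to 12.22 in D2 (adjusted p = 6.35e-10). The complement gene C1qb ranged over 5.78 (adjusted p = 1.21e-04), with 9.29 and 6.98 in the 2 D2 mice. Ifi202b ranged over at least 8.85 (adjusted p = 6.62e-06), with 3.92 and 9.80 in the 2 BXD14 mice. In all 2941 genes differed, 1281 of them by at least 2-fold between the highest and lowest strain.

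The genes that differed were unevenly spread over the lists by Fisher's exact test. That test takes the genes of a list as independent, so its adjusted p-values may be too small where they are correlated. They made up 10 of 12 class II genes, 22 of 35 cytokines, 11 of 14 glycolysis genes and 11 of 13 macrophage markers (adjusted p = 0.00631 for each) (11, 23, 12 and 11 adjusted over the list alone). NF-kappaB genes (16 of 25, adjusted p = 0.0123), cholesterol genes (12 of 17, adjusted p = 0.0124), maturation genes (14 of 22, adjusted p = 0.0197) and receptors (15 of 24, adjusted p = 0.0229) were also enriched, and respiratory genes depleted (3 of 33, adjusted p = 0.007). Interferon-stimulated genes differed in 10 of 36 (adjusted p = 0.671), with a median range of 0.43. No gene passed in a limma comparison of the 6 BXD strain means with the parental means, and 117 had an unadjusted p under 0.05. In camera on that comparison, macrophage markers (median -0.30) and glycolysis genes (median -0.19) were lower in the BXD strains (adjusted p = 6.59e-04 for both, or adjusted p = 0.99 with an estimated correlation for both). Over 222 genes that differed between the parents, the median position of a strain between D2 (0) and B6 (1) was 0.796 in BXD2, 0.725 in BXD40, 0.703 in BXD14, 0.621 in BXD5, 0.515 in BXD16 and 0.384 in BXD28. Positions of single genes spread widely (quartiles of 0.138 and 0.957 in BXD5). Over the 62 genes with a parental difference of at least 2, BXD14 lay at 0.407 and BXD5 at 0.448. Of these genes 48.4% and 50% lay nearer B6, so neither strain stood clearly nearer to either parent.

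**Figure D4:**
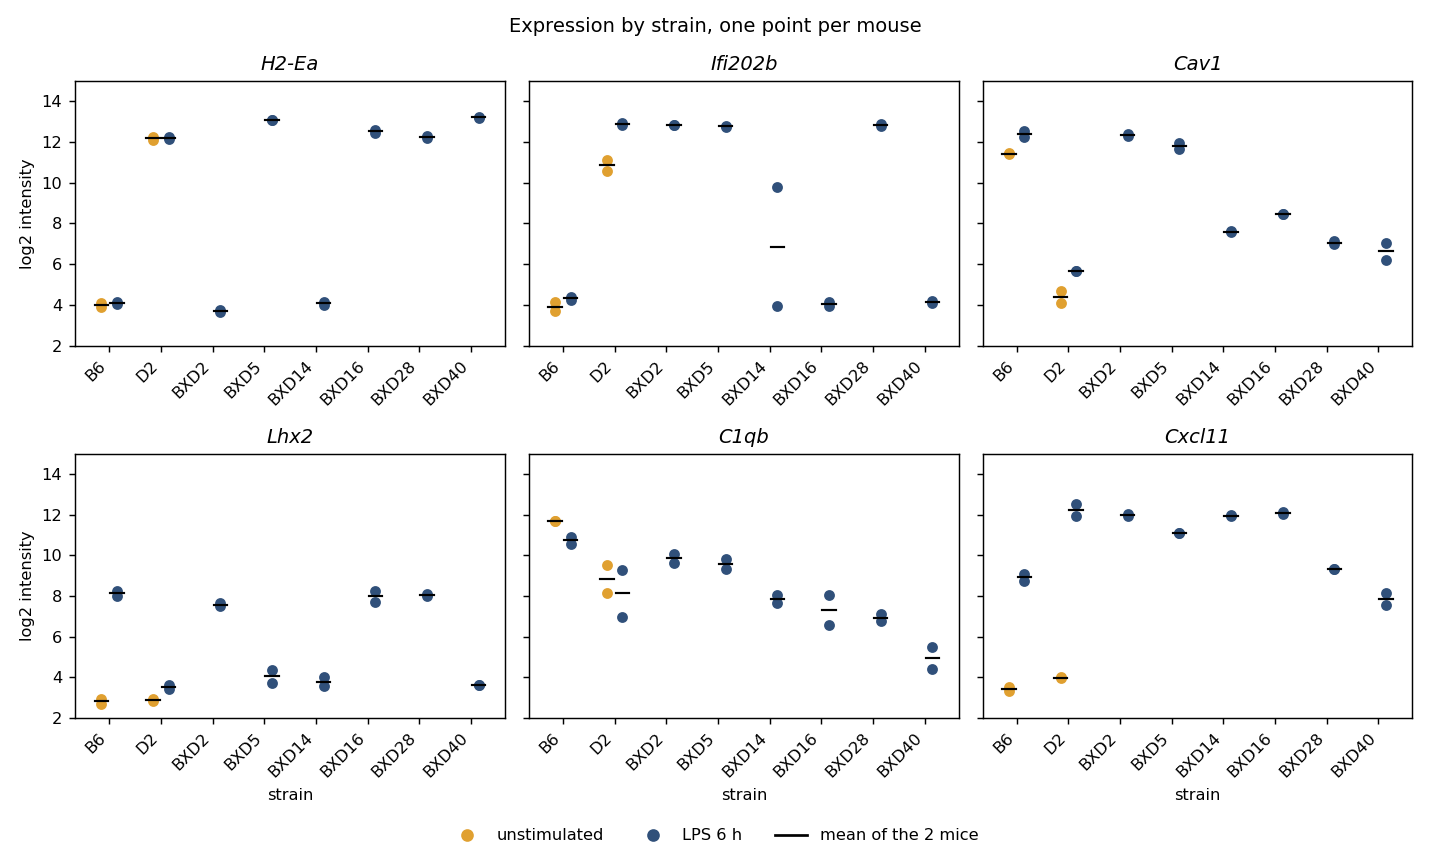
Log2 intensity of H2-Ea, Ifi202b, Cav1, Lhx2, C1qb and Cxcl11 (vertical axis) in the 8 strains (horizontal axis), with 1 point per mouse and lines at the mean of 2 mice. Orange points are unstimulated and blue points 6 h of LPS; the mean of Lhx2 is 8.13 in B6 and 3.52 in D2.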

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

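The tests below for degraded RNA, for a response shared by the 3 ligands (with its split of the unstimulated mice) and for probe sequence in genes higher in D2 were chosen after the results were seen, as were the splits of arrays without strain in the fit. The comparisons between times of PAM and polyIC were also added after the data were seen.

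The response to 6 h of LPS differed between B6 and D2 for 444 genes, by a test of the difference itself. It was larger in B6 on the signed scale for Lhx2 (4.67), Lta (3.94), Rnd3 (3.89), Slfn1 (3.61), Riox2 (2.90), Pttg1 (2.84) and Ifi205 (2.73). Rnd3, Riox2 and Pttg1 went up in B6, by 2.32, 1.86 and 1.78, and down in D2, by -1.57, -1.04 and -1.07. Interferon-stimulated and Ifi200 genes on this side were Oasl2 (2.4), Rtp4 (2.25), Ifitm3 (2.01), Ifi203 (1.09) and Ifi209 (1.02). The cytokines Il6 (2.10), Ccl4 (2.08) and Cxcl1 (2.08) and the cell-cycle genes Mki67 (1.62), Bub1 (1.19) and Mcm6 (1.18) stood there too, the last 3 because D2 moved further down (-1.10, -2.95 and -2.10, against 0.52, -1.76 and -0.92 in B6). On the D2 side were Cxcl11 (-2.74), Gbp2b (-2.55), Cd72 (-2.48), Acpp (-2.33) and Il33 (-2.26), which rose more in D2, and Stab1 (-2.56), which fell more in B6 (-3.21 against -0.65). Sizes are uncertain where levels lay under the filter level, which applies to Lhx2, Lta, Cxcl1, Bub1, Cxcl11, Acpp and Il33. The count was 206 or 269 without B6 LPS replicate 1 or 2, 266 or 248 without B6 unstimulated replicate 1 or 2, and 277 or 279 without replicate 2 of D2 at rest or after LPS. It was 283 when arrays were centred on housekeeping genes.

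For several of the genes on the B6 side the strains differed at rest and lay close after LPS, so their values do not by themselves show a stronger response. Rtp4 lay at 7.56 in B6 and 9.82 in D2 at rest and at 11.75 in both after LPS, and Ifitm3 at 9.68 and 11.75 at rest and at 12.68 and 12.73 after LPS. In B6 and D2, Il6 lay at 4.32 and 6.25 at rest and at 13.12 and 12.95 after LPS, Ccl4 at 6.56 and 8.78 and at 12.42 and 12.55. Cxcl1 lay at 3.61 and 6.10 and at 11.36 and 11.76. Oasl2 lay at 6.20 and 8.31 at rest and at 11.30 in B6 after LPS, close to D2. Ifi203 lay at 5.81 and 6.96 and at 10.69 and 10.74. Starting level, a limit of the signal and a different response were not tested apart. Lhx2 and Cxcl11 lay apart after LPS (8.13 and 3.52; 8.92 and 12.22), but at rest both lay under the intensity asked of tested genes in either strain (2.82 and 2.88; 3.42 and 3.98). Their starting levels therefore cannot be compared. A technical explanation for strain differences on an array is sequence under the probes. Probes designed on B6-like sequence would lose signal in D2, but 53.4% of the genes called at rest were higher in D2. Other probe sets were measured for 157 of the 480 genes higher in B6, and 88.1% of them were also higher in B6, against 48.3% for genes not called. This argues against single bad sites as the only source in those 157 genes. The median difference at the other probe sets was 0.42, against 0.82 at the reported ones, so part of the size may come from the probes. Genes higher in D2 also had a smaller median there, -0.44 against -0.67. Called genes were picked by their reported probe sets, which can by itself make the others smaller, so the sizes cannot decide. The remaining genes were not tested this way. Single genes may still be affected, and a biological difference between the strains stays open, since genotype was not tested beyond the strain names. The 35 splits of the 8 LPS and unstimulated parental arrays into 4 and 4 gave 5979 genes for the real split and 0 at most for any other (1 of 35 as large). That fit holds strain, and other splits carry the LPS effect in their residuals. On these 8 arrays alone without strain the real split gave 5235 and the highest other, by strain, 116 (again 1 of 35 as large). The other splits carry the LPS effect in their residuals here too, and 1 of 35 is the smallest share possible. Chance is therefore an unlikely source of the LPS calls, but these splits cannot exclude it.

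Time also mattered within a ligand, with 3342 genes differing between 6 h and 2 h of LPS, 1005 for PAM and 772 for polyIC. Without the B6 array at 2 h of LPS the first count was 2107. The second was 287 without the B6 PAM pool at 6 h, 370 without the D2 pool at 6 h and 359 without the PAM library titled D2 at 2 h. The third was 353 without the B6 polyIC pool at 6 h, 327 without the D2 pool at 6 h and 364 without the polyIC library titled D2 at 2 h. The LPS comparison sets individual mice against each other and the other comparisons set pools against pools.

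Some RNAs fell whichever pool was compared with unstimulated cells. There were 206 genes called lower and 57 called higher in all 4 pooled conditions. These counts were not set against chance because the 4 comparisons share their unstimulated arrays. The lower genes, which the tests that follow concern, include Fubp1, Airn, Neat1 and Erdr1. Degraded RNA in the pools would raise the 3' over 5' difference of the control probe sets, but that difference changed by -0.0498 (log2), at 0.118 (SD 0.0568) in pools and 0.168 (SD 0.0316) in other arrays. A response common to the ligands was tested with separate controls, choosing genes against 1 unstimulated mouse per strain and measuring LPS against the other. The 149 and 73 genes chosen in these 2 ways changed by a median of -0.70 and -0.67 after 6 h of LPS, in individual mice, where the remaining genes had medians of -0.13 and -0.12. After 2 h the medians were -0.32 and -0.42. Most of these genes were thus also lower after 6 h of LPS (89.9% and 86.3%, against 56.9% and 56.3% of the remaining genes). Both sets of controls are unstimulated arrays, and a difference common to all of them would give the same fall. The split therefore cannot tell a response shared by the ligands from such a difference. Lower recovery of nuclear noncoding RNA in the pools stays open. Only 2 listed RNAs had not been seen before, and Snhg5 (-0.81) and Meg3 (0.17) gave a median of -0.319. Whether each listed RNA is mainly nuclear in these cells was not measured. Outside the pools, Airn, Neat1, Xist, Gas5 and Snhg5 fell by 1.59, 1.65, 1.34, 1.88 and 1.69 after 6 h of LPS (Meg3 changed by 0.50), which argues against loss in pools as the only reason. After 2 h of LPS the changes were -0.66, 0.65, 0.01, -0.18 and -0.87, and the unstimulated arrays are shared. Pooling and ligand cannot be told apart for PAM and polyIC against unstimulated cells, since none of the 8 pools is unstimulated.

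Expression differed among the 8 strains after LPS, which raises what lies behind the 2941 genes. Called genes next to each other along a chromosome correlated across strain means at 0.0790 on average, above the highest of 1000 random orders (0.0331; permutation p = 0.001, the smallest that 1000 orders can give). This is consistent with parental haplotypes shared by neighbours. Cross-hybridisation between related neighbours would remove that excess when pairs with like symbols are left out, but it remained at 0.0660 against at most 0.0291. A different share of macrophage-like cells would end most calls once the marker mean of each array is a covariate, if that mean follows the share. With it 2610 genes were called, 88.7% of the count without it, and 2450 were called both ways. The marker mean had an SD of 0.518 between and 0.331 within strains. Of the markers called between the parents at rest, C1qb (2.86) and Mertk (1.31) were higher in B6 and Marco lower (-3.00). Such markers cancel in a mean, so this test cannot decide on the share of these cells.

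Probe sets with no gene listed also carried signal. Of 2793 tested, 1844 were called after 6 h of LPS, 739 up and 1105 down. The highest rises were 7.19 ± 0.35 (adjusted p = 2.22e-08) and 6.10 ± 0.23. No gene was assigned to them.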

How the results depend on the processing

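The alternatives that add the pools as a second contrast, that leave out the pools or that use the macrophage covariate, and all settings of PAM against polyIC at 2 h and of 6 h against 2 h of PAM or polyIC, were chosen after seeing the data. Of 165 values of comparisons under alternatives other than leaving out arrays, 145 stayed within 1.5 times (or within their spread) and 20 moved. Of 10155 values of named genes, 9797 kept direction and call, 356 lost the call and 2 reversed. The reversals were Tapbp between LPS and polyIC at 6 h with housekeeping centring (-0.10) and Ifi209 between unstimulated B6 and D2 with averaged probe sets (1.27). Leaving out arrays lost the call of 983 of 7806 such values and reversed none. The cause was not tested.

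Housekeeping centring gave 2674 genes for PAM against polyIC at 6 h, 2033 for B6 against D2 after LPS and 283 for the interaction. Array weights gave 1632 for 2 h of PAM, 382 for PAM against polyIC at 2 h and 585 for 6 h against 2 h of PAM. A fit to only the compared arrays gave 259 for the interaction, with fewer degrees of freedom. Asking calls to differ also from the other pool left 695 for 6 h of PAM and 604 for polyIC, by construction fewer. List tests passed 143 times at the preset correlation, 19 times with an estimated correlation and 179 times with fry. With parental differences of at least 2, the positions were 0.741 (BXD2), 0.448 (BXD5), 0.342 (BXD28), 0.782 (BXD40), 0.407 (BXD14) and 0.645 (BXD16). With differences of at least 1, the label check gave 100% (LPS 2 h), 98.7% (polyIC 6 h), 1.89% (PAM 2 h) and 1.26% (polyIC 2 h). Except where construction shows it, the cause was not tested.

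Leaving out 1 array, with a lone array assumed to vary like the other groups, gave ranges of 5665 to 5813 genes for 6 h of LPS, 2487 to 3651 for 2 h of LPS, 1346 to 2584 for 6 h of PAM and 1163 to 2208 for 6 h of polyIC. The ranges were 2107 to 3283 for LPS at 6 h against 2 h, 2424 to 3761 for LPS against polyIC, 632 to 740 for PAM against polyIC, 1529 to 2388 for 2 h of PAM and 170 to 403 for 2 h of polyIC. They were 493 to 1287 for PAM against polyIC at 2 h, 287 to 1221 and 327 to 669 for 6 h against 2 h of PAM and polyIC, 620 to 805 and 741 to 1027 for B6 against D2 at rest and after LPS, and 206 to 334 for the interaction. The 8 strains gave 2196 to 3133. Positions ranged from 0.800 to 0.818 (BXD2), 0.636 to 0.637 (BXD5), 0.391 to 0.412 (BXD28), 0.697 to 0.708 (BXD40), 0.703 to 0.739 (BXD14) and 0.527 to 0.541 (BXD16). Fewer arrays were the construction of these settings.

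Numbers in the descriptions were tried as a replicate block, though mouse differences correlated at 0.0858 in B6 and 0.307 in D2 across genes between unstimulated and LPS arrays. It gave 5809 genes for 6 h of LPS, 3106 for 2 h, 2900 for 6 h against 2 h and 418 for the interaction. Array signal over background limits dim genes, of which 3331 were not tested.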

Other observations

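Differences between mice of a group were computed after the data were seen, and the genes named from them were chosen after their values were seen.

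Ifi202b, an Ifi200 gene that is high in D2 and low in B6, differed between the 2 BXD14 mice after LPS, at 3.92 in 1 mouse and 9.80 in the other. Across the 10 groups with 2 mice it was the only gene that differed at least 8-fold between mice of a group, and the next gene in BXD14, Slc27a3, differed by -1.81. The other 4 measured family members lay together in both mice: Ifi203 at 10.82 and 10.78, Ifi204 at 9.20 and 9.47, Ifi205 at 12.79 and 12.89, and Ifi209 at 12.30 and 12.28. In the other strains Ifi202b lay at 12.89 (D2), 12.86 (BXD2), 12.82 (BXD28) and 12.78 (BXD5), or at 4.31 (B6), 4.15 (BXD40) and 4.03 (BXD16).

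Mice of a group differed at least 2-fold in 4 (BXD28) to 170 (BXD40) genes. In BXD40 the widest were Apoe, a lipid carrier, at 7.20 and 9.99, and Egr1 at 9.34 and 6.77. In D2 after LPS it was the complement gene C1qb at 9.29 and 6.98, and in unstimulated D2 the protease inhibitor Serpinb2 at 10.11 and 7.85.

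Several genes fell into separate high and low levels across the 8 strains after LPS. Pttg1 lay between 12.15 and 12.25 in B6, BXD5, BXD16 and BXD40 and between 7.70 and 7.83 in the others. Trim12a lay between 7.42 and 7.55 in B6, BXD2, BXD16 and BXD40 and between 3.00 and 3.17 in D2, BXD5, BXD14 and BXD28. Cxcl11 was low in B6 (8.92), BXD28 (9.32) and BXD40 (7.85) and above 11 in the others.

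The comparison of the 6 BXD strains with the parents called 0 genes in limma, with 117 at an unadjusted p under 0.05. All 28 splits of the 8 strains into 6 and 2 therefore gave as many or more by construction, and they say nothing about chance. The highest of the other splits, D2 and BXD16 against the rest, called 74 genes. That count may point to a structure of the strains, but the split was picked as the highest and was not tested further.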
